A study of Mus musculus with 96 samples.

How the data were processed

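The data are the processed files of this series, which the authors deposited with TPM tables, and no reads were used here. Per the labels, organoids of 4 genotypes were treated with 0.1 µM dexamethasone for 1 h, moved to fresh medium and collected every 2 h from 24 to 46 h, with 2 libraries per group. The labels name 96 libraries. The design written before the data were examined counted 24 libraries per genotype, and the TPM tables hold 22, so all tests used 22, 44 or 88 libraries. In 8 groups 1 library was left, and the 8 libraries that the authors marked as not used had 13.55 to 32.49 M uniquely mapped reads. RNA was made into directional libraries and sequenced as single reads of 101 bases per the labels.

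The TPM values were deposited by the authors as a table for each genotype from RSEM, and their processing notes list STAR 2.5, RSEM 1.3.0 and GRCm38 without a role or an order. Column sums ran from 999999.2 to 1000001.03. The quantile-normalized TPM tables, filtered by the authors within each genotype, were deposited with 15311 to 15772 genes and served only as an alternative. The read counts in the alignment table are, per the file headers, the numbers of input and uniquely mapped reads that the aligner logged, with no normalization by the authors. The percent values in that table are, per the file headers, shares of reads or bases from the same aligner log, deposited as logged. A text column of that table says whether the authors used the library, and it was taken as deposited. The tables hold 55536 gene IDs, of which 55450 have a symbol in GENCODE M21, and 217 IDs that share a symbol were kept apart by ID.

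Tests were chosen before the data were examined. TPM was transformed as log2(TPM + 1), and genes with a mean of 1 TPM or more in at least 1 of the groups compared were tested. Rhythm within a genotype was tested in limma (version 3.58.1, with a variance trend) by an F test of a cosine and a sine term of 24 h period, over the 22 libraries. A single 24 h cycle was sampled, so the test cannot tell a cosine from another change that happens once in the series. A rhythm difference was the F test in limma of the genotype by cosine and sine terms over 44 libraries. Mean level was compared in limma with the time point as a factor, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of 1 or more, which is 2-fold. The interaction of Apc and Bmal1 was tested over the 88 libraries. "Rose" and "fell" for members of a list mean adjusted p under 0.05 over all genes. The direction of each comparison is mutant over WT. Adjusted p-values of genes are over all genes tested in the comparison, those of list tests over all 125 list tests. Error values are standard errors of the limma coefficient unless SD is given.

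Gene lists were fixed at the same stage, 36 in all. They cover core clock, E-box clock targets, REV-ERB and ROR clock targets, glucocorticoid response, intestinal stem cell, Wnt targets, Hippo pathway components, YAP targets, fetal and regenerative epithelium, Notch pathway, Paneth, goblet, enteroendocrine and tuft cells, enterocytes, proliferation, p53 targets, interferon response, inflammation and antimicrobial genes, unfolded protein and integrated stress response, heat shock, glycolysis and hypoxia, cholesterol synthesis, PPAR targets and fatty acid oxidation, mitochondrially encoded genes, replication-dependent histones, fibroblasts, immune cells, endothelial cells, smooth muscle, neurons and glia, gastric epithelium, colon epithelium, proximal small intestine, ileum, and sex-linked genes. Lists with 3 or more tested members were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation. Of 125 list tests 51 were called at the preset and 16 with the estimated correlation.

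Named genes followed a rule set before the data were examined. It takes Arntl and Apc first, all core clock genes for rhythm, and in each genotype the 10 rhythmic genes of lowest adjusted p with a fitted swing of 1.5-fold or more. For mean level it takes the 10 largest differences in each direction with the same sign at all 12 time points and 5 TPM or more in the higher genotype, without predicted genes. For rhythm differences and the interaction it takes the 10 of lowest adjusted p, and for lists up to 4 members with the largest difference. Other genes are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here. The lower-numbered and higher-numbered libraries are the sets formed in each group by library number. The axis of Bmal1 genotype was chosen after the data were seen and was computed without the pair of doubted libraries.

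The scripts were checked on simulated changes in 200 genes. A 2-fold rhythm was recovered in 82, 98, 74 and 78% of 50 genes in control, Bmal1-null, Apc-min and Apc-min Bmal1-null organoids, with 6.92, 4.96, 2.78 and 4.46% false calls. A 2-fold level difference was recovered in 98 to 100%, and a 2-fold rhythm difference in 56 to 78%. The simulated noise was drawn independently for each gene and library, so these shares do not carry over to data whose libraries share structure. In the real data, random orders of the time labels called up to 988, 5549, 4787 and 805 genes in the same 4 genotypes. Analyses ran in R 4.3.3 with version 1.17.8 of data.table, and figures and tables in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.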

Results

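Gene expression was measured by RNA-seq in mouse intestinal organoids, self-organising epithelial cultures derived from C57BL/6 mice, to ask which genes cycle after the clocks of the cells are synchronized. The labels name 4 genotypes that combine wild-type (WT) Apc or the genotype APCmin/-, as labelled, with WT or null Bmal1. Apc restrains Wnt signalling, and Bmal1 (gene symbol Arntl) is a transcription factor the circadian clock depends on. The 4 genotypes are called here control, Bmal1-null, Apc-min and Apc-min Bmal1-null organoids. Each genotype was sampled every 2 h from 24 to 46 h after 1 h of dexamethasone, a glucocorticoid that brings cells to a common clock phase. The expression tables hold 22 libraries per genotype, 88 in all, with 1 or 2 libraries at each of the 12 time points. The labels give 2 organoid lines per genotype but not the line of each library, so every p-value covers the spread between libraries and not between lines. The 88 libraries held 28.8 to 48.1 M uniquely mapped reads, with a mean of 35.9 M ± 3.94 (SD, n = 88). Apc-min cultures grew in EN medium and the others in ENR, which also holds the Wnt agonist R-spondin, so the Apc comparisons are also comparisons of media. They are also comparisons of library series, as Apc-min libraries carry numbers 1 to 48 and the others 49 to 96, and reads unmapped as too short averaged 1.299 and 1.305% in the Apc-min genotypes against 6.73 and 6.00% in the others.

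Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126 on the plus strand, GRCm38) averaged 14.9 TPM ± 2.74 in control and 8.67 TPM ± 1.14 in Bmal1-null organoids (SD, n = 22 each). It averaged 11.1 TPM ± 3.44 in Apc-min and 4.86 TPM ± 2.42 in Apc-min Bmal1-null organoids (SD, n = 22 each). Gene-level TPM cannot show which part of the gene was removed. Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333 on the minus strand), which encodes the clock repressor REV-ERB alpha and is a direct Bmal1 target, averaged 17 TPM ± 5.86 in control and 2.39 TPM ± 0.455 in Bmal1-null organoids. Apc (ENSMUSG00000005871, chromosome 18, 34220924 to 34322552 on the plus strand) averaged 9.50 TPM ± 3.25 and 8.80 TPM ± 2.77 in the genotypes WT for Apc. It averaged 14.9 TPM ± 4.44 and 15.4 TPM ± 4.43 in the Apc-min genotypes (SD, n = 22 each).

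A pair of Apc-min libraries at 28 h did not match their Bmal1 labels. On an axis over 1060 genes that runs from 0 at the mean of the Apc-min libraries to 1 at the mean of the Apc-min Bmal1-null libraries, the library labelled Apc-min 28 h replicate 1 scored 0.99, where the other 21 libraries of that genotype scored -0.31 to 0.29. The library labelled Apc-min Bmal1-null 28 h replicate 1 scored -0.23, where the other 21 scored 0.93 to 1.06. Arntl itself was at 4.09 TPM in the former library, the lowest of its labelled genotype. It was at 14.7 TPM in the latter, the highest of its labelled genotype, which widens the SD given above. Both were kept under their labels, and the counts of rhythmic genes, of rhythm differences and of 2-fold differences between genotypes are also given without both. The levels and log2 differences of single genes include both.

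**Figure D1:**
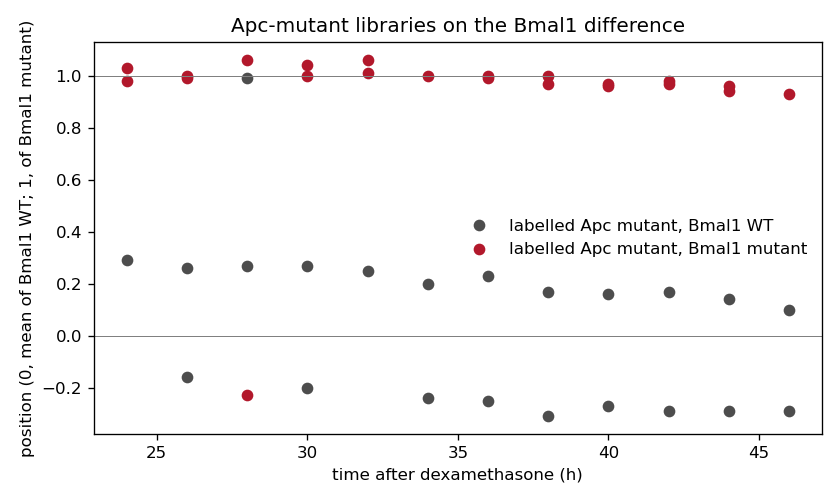
Position of each Apc-min library on the axis from Bmal1 WT (0) to Bmal1-null (1) against hours after synchronization, 1 point per library, coloured by label. The library labelled Apc-min at 28 h sits at 0.99 and the one labelled Apc-min Bmal1-null at -0.23.

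In control organoids clock genes passed the rhythm test. Nr1d1 swung 2.16-fold from peak to trough and peaked at 25 h (log2 amplitude 0.55 ± 0.08, SE, n = 22), and Tef and Dbp, output regulators of the clock, swung 2.20-fold and 1.69-fold with peaks at 30.4 and 29.6 h. They were among the 4 core clock genes that passed the 24 h cosine test in limma (adjusted p = 0.0107 to 0.0154), of 19 tested. Adjusted over the list alone, 11 of the 19 passed. The others were the repressors Per2 (peak at 31.5 h, amplitude 0.37 ± 0.09), Per3 (30.5 h, 0.32 ± 0.06), Cry1 (34.4 h, 0.28 ± 0.06), Cry2 (32.1 h, 0.34 ± 0.07) and Ciart (30.5 h, 0.19 ± 0.06), with Nr1d2 (28.6 h, 0.51 ± 0.10) and Nfil3 (38.7 h, 0.18 ± 0.05). Arntl had an amplitude of 0.14 ± 0.07 and did not pass (adjusted p = 0.494). Over all genes, 7 of 12570 passed, among them also Tmem252 (1.57-fold, peak at 40.6 h), the carboxylesterase Ces1d (2.29-fold, 36.8 h) and the chloride channel Ano1 (2.38-fold, 28.5 h). At an unadjusted p under 0.05 there were 1539 genes. The count was 4 without the 30 h replicate 1 library, 12 without 46 h replicate 1 and 50 without 46 h replicate 2. It was 0 within either the lower-numbered or the higher-numbered libraries alone, but 289 (3366 unadjusted) with the lower- or higher-numbered library as a term. It was 11 with no filter on low values, 4 at a mean of 5 TPM or more, 30 with median-of-ratios scaling and 45 in the authors' quantile-normalized table. With a linear time term it was 4, with time as a factor 2 and with the slope on gene length as a covariate 52.

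In Bmal1-null organoids no clock gene passed the rhythm test. None of 12550 genes passed in limma (864 at an unadjusted p under 0.05), and 0 of 19 clock genes passed adjusted over the list alone. The amplitude of Nr1d1 was 0.03 ± 0.06, of Tef 0.05 ± 0.06 and of Dbp 0.06 ± 0.05 (log2, SE, n = 22). The median amplitude of the clock genes was 0.05, against 0.28 in control organoids. Nfil3, with 0.11 ± 0.03, had the lowest p of the list (adjusted p = 0.267). Without 46 h replicate 1, 46 h replicate 2 or 42 h replicate 2 the count was 10, 5 or 1 gene. With time as a factor of 12 levels in place of the cosine, 25 genes passed, and with the slope on gene length as a covariate 172 (2257 unadjusted). The count was 7 in the authors' quantile-normalized table.

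**Figure D2:**
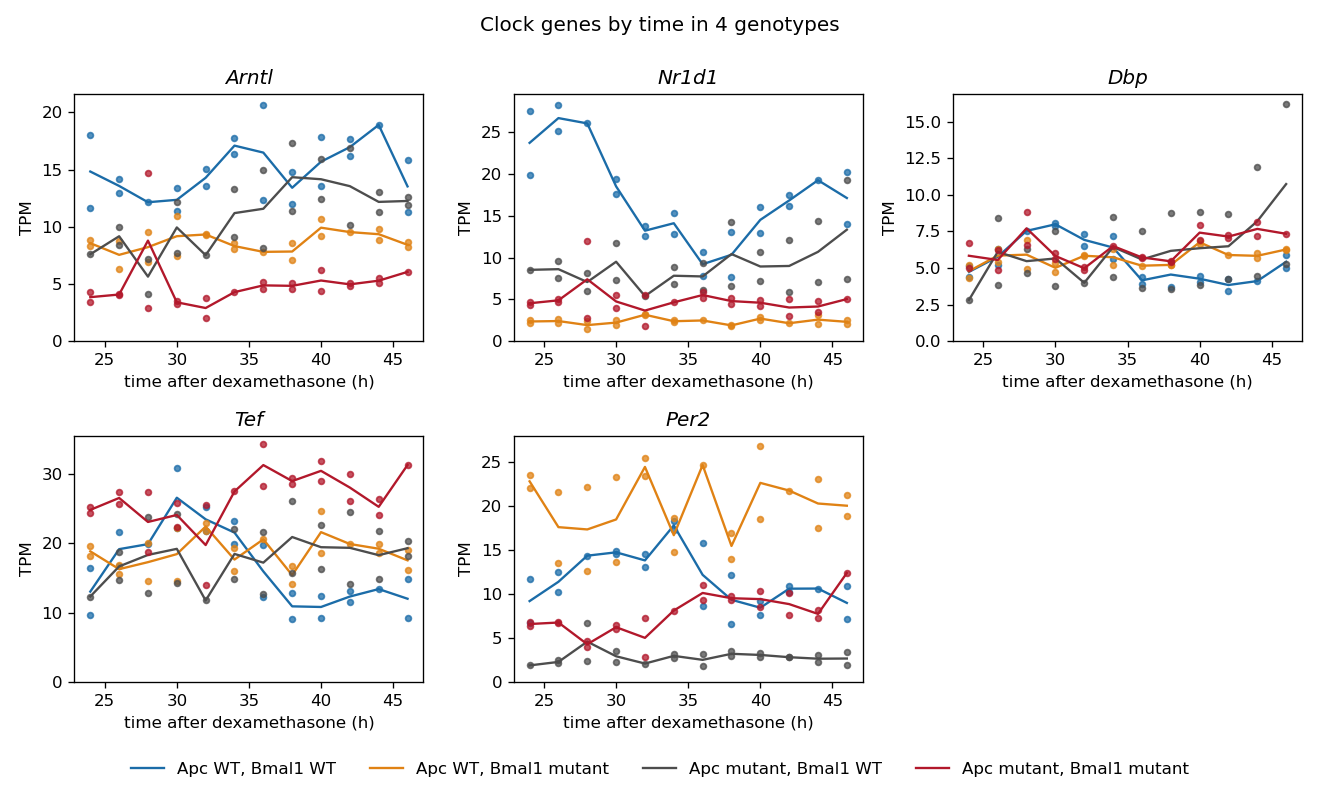
TPM of 5 clock genes against hours after synchronization in the 4 genotypes, where points are libraries and lines are means per time point. Nr1d1, Tef and Dbp rise and fall in control organoids with fitted peaks at 25 to 30.4 h, and stay level in Bmal1-null organoids.

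The loss of rhythm was tested directly. The 24 h rhythms of Nr1d1 and Dbp (adjusted p = 0.0363 each), Tmem252 (0.04) and Tef (0.041) differed between control and Bmal1-null organoids in limma's interaction test. They were among the 5 genes that passed of 12654, with 237 at an unadjusted p under 0.05. Of the 19 clock genes, 4 passed over all genes and 11 adjusted over the list alone, which adds Per2, Per3, Cry1, Cry2, Nr1d2, Ciart and Bhlhe40. The count of 5 was 0 without any single library among control 26 h replicate 1, both of 30 h, both of 32 h and 34 h replicate 2, and Bmal1-null 30 h replicate 1, 34 h replicate 1 and both of 40 h. It was 1 without control 24 h replicate 1 or Bmal1-null 34 h replicate 2. It was 2 without control 34 h replicate 1, 38 h replicate 2 or 46 h replicate 2, or Bmal1-null 24 h replicate 2, 26 h replicate 1 or 46 h replicate 2. It was 3 without control 40 h replicate 1, 40 h replicate 2 or 42 h replicate 2, or Bmal1-null 24 h replicate 1, 28 h replicate 1, 28 h replicate 2 or 44 h replicate 1. It was also 0 with no filter on low values, 1 with a linear time term or with all 88 libraries in the fit, and 3 with a pseudocount of 0.1.

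In Apc-min organoids many genes passed the cosine test, and most peaked late in the series. Hif3a, a hypoxia-inducible factor subunit, swung 3.93-fold with its peak at 41.4 h (amplitude 0.99 ± 0.17, SE, n = 22), and Ace, angiotensin-converting enzyme, swung 2.68-fold. The thyroid hormone receptor Thra (1.77-fold), the mitochondrial carrier Slc25a23 (2.18-fold), the O-GlcNAc transferase Ogt (2.12-fold), the phosphatidate phosphatase Lpin1 (2.07-fold), the adenosine receptor Adora1 (2.07-fold), the copper transporter Atp7b (2.07-fold), the splicing factor Srrm2 (1.58-fold) and the zinc finger gene Zfp950 (1.72-fold) were the other top genes. All 10 peaked between 39.8 and 41.5 h (adjusted p = 0.0153 to 0.0163). In all, 1513 of 12625 genes passed in limma, of which 1266 peaked within 3 h of 41 h and 228 within 3 h of 29 h. Together these are 98.7%, and 41 h and 29 h are the times at which a rising or falling straight line over the series would place the peak. Such peak times were not particular to Apc-min organoids. Among genes at an unadjusted p under 0.05 the share was 95.6% in control and 90.9% in Bmal1-null organoids. It was 96.4% in Apc-min and 93.9% in Apc-min Bmal1-null organoids. Of 20 clock genes, Arntl alone passed (1.79-fold, peak at 40.3 h, adjusted p = 0.024), and 5 passed adjusted over the list alone, with Per1, Bhlhe40, Nfil3 and Ciart. None of the 4 clock genes that passed in control organoids passed here. With a linear time term added, 0 genes passed (345 at an unadjusted p under 0.05), and 0 passed with time as a factor (428). The count was 401 without the library labelled 28 h replicate 1, which is the value without both doubted libraries, and Arntl was then not called. It was 494, 2643, 704, 742, 517, 759, 403 and 876 without 28 h replicate 2, 30 h replicate 1, 30 h replicate 2, 32 h replicate 2, 38 h replicate 1, 40 h replicate 1, 42 h replicate 1 and 44 h replicate 1. Within the lower-numbered or the higher-numbered libraries alone it was 0. It was 4179 with the lower- or higher-numbered library as a term, 5658 with the slope on gene length as a covariate, 587 with no filter on low values and 797 in the authors' quantile-normalized table.

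In Apc-min Bmal1-null organoids 316 of 12206 genes passed. The inflammasome sensor Nlrp6 swung 4.92-fold (amplitude 1.15 ± 0.14, SE, n = 22), the stem cell marker Smoc2 3.82-fold, the chloride channel regulator Clca3b 3.74-fold and the sodium-proton exchanger Slc9a3 3.26-fold. Mlxipl, the carbohydrate-response factor ChREBP, had the lowest adjusted p in limma (0.000336, 2.35-fold), and Stc2 (2.81-fold), Lzts3 (2.12-fold), the acetyl-CoA synthetase Acss1 (2.54-fold), Sept5 (2.20-fold) and St6galnac2 (2.06-fold) completed the top 10. Their peaks lay between 40.5 and 41.6 h. Of 19 clock genes, 5 passed over all genes and 6 adjusted over the list alone. Among them were Npas2, a paralog of Clock (2.74-fold, 41.1 h), Ciart (41.9 h), Per2 (40.7 h) and Nfil3 (43.2 h), with Cry2 in the list alone. Per2 had peaked at 31.5 h in control organoids. With a linear time term 0 genes passed (286 at an unadjusted p under 0.05), and 2 passed with time as a factor. The count was 1444 without the library labelled 28 h replicate 1, the value also without both doubted libraries, and 8 clock genes then passed. It was 202, 196, 204, 151, 202, 195 and 194 without 26 h replicate 1, 28 h replicate 2, 38 h replicate 2, 40 h replicate 2, 42 h replicate 1, 44 h replicate 1 and 44 h replicate 2. Within the lower-numbered libraries it was 0 and within the higher-numbered 81, and with the slope on gene length as a covariate it was 1219.

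No rhythm difference was found between Apc-min and Apc-min Bmal1-null organoids, with 0 of 12885 genes in limma and 880 at an unadjusted p under 0.05. Without the doubted libraries these were 0 and 300. No clock gene of 20 passed adjusted over the list alone. The count was 1 without Apc-min 30 h replicate 1, 34 h replicate 1, 36 h replicate 2 or 38 h replicate 2 or Apc-min Bmal1-null 40 h replicate 1, and 2 without Apc-min Bmal1-null 46 h replicate 1. With all 88 libraries in the fit it was 13, and with the lower- or higher-numbered library as a term 4.

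Loss of Bmal1 in organoids WT for Apc shifted the level of a small set of genes, among them clock genes and sex-linked genes. The repressors Nr1d1 and Nr1d2 fell by 2.38 ± 0.10 and 1.92 ± 0.11 on the log2 scale (SE, n = 22 per genotype), Nr1d2 from 10 to 1.85 TPM. The clock repressors Cry1 and Cry2 rose by 1.245 ± 0.07 and 1.254 ± 0.08. In limma 21 of 12654 genes differed at least 2-fold, 10 higher and 11 lower in Bmal1-null organoids, and 450 passed the adjusted p alone. That last count was 184 with the library sets as blocks and 8 with set means as units.

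Other genes that rose were Tmem252 (1.76 ± 0.05), the tight junction claudin Cldn8 (1.64 ± 0.07), the antimicrobial lectin Reg3b (1.37 ± 0.13, from 477 to 1194 TPM), the drug-metabolizing cytochrome Cyp3a11 (1.23 ± 0.06), Smcp (1.15 ± 0.07) and the reelin adaptor Dab1 (0.98 ± 0.10). Among those that fell were Igfbp4, an insulin-like growth factor binding protein (-2.13 ± 0.06, from 61.6 to 13.3 TPM), the chloride channel gene Clic6 (-0.77 ± 0.08), the phosphodiesterase Smpdl3a (-0.75 ± 0.05), Arntl (-0.70 ± 0.06), Mterf2 (-0.66 ± 0.05) and the ferric reductase Cybrd1 (-0.60 ± 0.09). The Y-linked Eif2s3y and Ddx3y also fell, by 2.83 ± 0.67 and 2.03 ± 0.46. Each of these had the same sign at all 12 time points, with limma adjusted p from 2.4e-25 to 0.00748. Named after their values were seen, further 2-fold calls were Ces1d (-1 ± 0.09), Xist, Kdm5d, Uty, Gm29650, Gm28588 and Rps13-ps2. Xist was read in the higher-numbered libraries of both Bmal1-null genotypes (11 and 10 libraries, means of 67 and 64 TPM) and Y-linked genes in all other libraries, so the sex-linked genes moved with the library set as well as with the genotype.

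Of the 6 REV-ERB and ROR clock targets 4 rose and 1, Arntl, fell, and the list was called upward (adjusted p = 3.65e-08, and adjusted p = 0.0339 with an estimated correlation). Among the rises were Cry1, the Clock paralog Npas2 (0.54 ± 0.11) and Nfil3 (0.39 ± 0.04). Of 19 core clock genes 6 rose and 4 fell (6 and 5 adjusted over the list alone), with Per2 at 0.74 ± 0.11, and of 12 E-box clock targets 3 rose and 3 fell (3 and 4), and neither list was called (adjusted p = 0.354 and 0.35). Of 8 fetal and regenerative epithelium markers 2 fell (3 adjusted over the list alone), Anxa10 (-0.41 ± 0.05) and clusterin, Clu (-0.25 ± 0.04), and the list was called downward (adjusted p = 1.05e-05, and adjusted p = 0.0313 with an estimated correlation). That call was lost with set means as units (adjusted p = 0.106). The sex-linked list was called (1 rose and 4 fell of 5, adjusted p = 0.000476, and adjusted p = 0.0423 with an estimated correlation). Interferon response (0 rose and 1 fell of 8, and 4 fell adjusted over the list alone), glycolysis and hypoxia (0 of 16) and tuft cell genes (0 of 10) were called downward. These calls were lost at adjusted p = 0.145, adjusted p = 0.667 and adjusted p = 0.5 with an estimated correlation. The interferon and glycolysis calls were also lost with set means as units (adjusted p = 0.121 and 0.113).

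The remaining lists were not called. Among 12 glucocorticoid response genes 2 rose and 1 fell (4 and 1 adjusted over the list alone), with the kinase Sgk1 at 0.42 ± 0.07 and Klf9 at -0.15 ± 0.04. Of 14 Paneth genes 2 rose, among them the ribonuclease Ang4 (0.31 ± 0.04), and 1 fell, the metalloproteinase Mmp7 (-0.23 ± 0.04). Of 11 goblet genes 1 rose (Zg16, 0.32 ± 0.05), and of 14 enteroendocrine genes 2 rose, among them Reg4 (0.51 ± 0.07). In the enterocyte list 2 of 20 rose and 3 fell, with lactase Lct at 0.45 ± 0.12 and Mgam at -0.26 ± 0.07. No gene of the Wnt target (16 tested), intestinal stem cell (17), Hippo (17), Notch (11), proliferation (20), p53 target (14), heat shock (8), unfolded protein response (12), cholesterol synthesis (19), mitochondrially encoded (7) or histone (6) lists passed in limma. Of the 30 lists, 21 had the same counts adjusted over the list alone, and the others differed by at most 3 members. Median, mean and test differed in sign for the Hippo, Notch, colon, core clock and ileum lists. With the means of the lower-numbered and higher-numbered libraries as units, 7 genes differed 2-fold in place of 21, and with a pseudocount of 0.1 there were 34. Of the 21, 11 were 2-fold in all 4 pairs of library sets.

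Loss of Bmal1 in Apc-min organoids coincided with wider differences in level. The keratin gene Krt14 fell by 3.65 ± 0.29 on the log2 scale (SE, n = 22 per genotype), from 511 to 73.2 TPM, and Krt6a by 3.67 ± 0.30. The growth factor Igf2 fell by 4 ± 0.33, from 22.6 to 0.821 TPM. In Apc-min Bmal1-null organoids Igf2 averaged 1.43 TPM in the lower-numbered libraries, which include a doubted one, and 0.092 TPM in the higher-numbered. The fatty acid binding protein Fabp2 (2.92 ± 0.28, from 6.50 to 41.1 TPM) and the duodenal transcription factor Pdx1 (4.06 ± 0.33, from 1.05 to 20.7 TPM) rose. In limma 827 of 12885 genes differed at least 2-fold, 247 higher and 580 lower, and 7769 passed the adjusted p alone. That last count was 1697 with the library sets as blocks (block correlation 0.329) and 1909 with set means as units, so the counts of list members that rose or fell rest on the fit without blocks. Without the doubted libraries 1021 did, 301 higher and 720 lower, and with quantile normalization the split was 317 higher and 434 lower. With a pseudocount of 0.1 the count was 1319.

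Among the largest rises were annexin Anxa10 (4.01 ± 0.34, from 1.70 to 29.7 TPM), the tetraspan proteins Tm4sf5 (3.51 ± 0.28) and Tm4sf4 (2.56 ± 0.26), the acyl-CoA synthetase Acsm3 (3.38 ± 0.26), Tmem238l (2.86 ± 0.23), Prap1 (2.86 ± 0.47), the brush border protease Mep1b (2.52 ± 0.18) and the brush border cadherin Cdhr2 (2.33 ± 0.20). The largest falls also held Bex4 (-3.98 ± 0.32), the chemokine Ccl2 (-3.38 ± 0.31), the lysozyme Lyz2 (-2.95 ± 0.24), Lect2 (-2.90 ± 0.23), the adaptor Grb10 (-2.88 ± 0.24), Eif2s3y (-2.75 ± 0.70) and Ppp2r2b (-2.57 ± 0.21). All had the same sign at the 12 time points (limma adjusted p = 7.18e-12 to 0.00115). Between pairs of library sets the Prap1 difference ranged from 0.41 to 4.84, that of Krt14 from -3.85 to -3.30 and that of Igf2 from -4.75 to -3.21. Of the 827 genes 812 (98.2%) had the same direction in all 4 pairs of library sets and 392 (47.4%) were 2-fold in all 4.

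Of 20 Wnt targets 15 fell and 3 rose (adjusted p = 0.00885, and adjusted p = 0.5 with an estimated correlation). Among them were the Wnt inhibitors Notum (-3.40 ± 0.41, from 167 to 21.3 TPM), Nkd1 (-2.52 ± 0.31), Apcdd1 (-2.26 ± 0.36) and Wif1 (-1.57 ± 0.31). The intestinal stem cell list went both ways (6 rose and 6 fell of 16, adjusted p = 0.675), with Lgr5 at -1.35 ± 0.21, Znrf3 at -0.78 ± 0.12, Hopx at 1.16 ± 0.18 and Slc12a2 at 1.02 ± 0.24. All 4 proximal small intestine markers rose, Pdx1, Gata4 (1.42 ± 0.14), the iron exporter Slc40a1 (1.19 ± 0.11) and Onecut2 (0.64 ± 0.15), with adjusted p = 0.000262, and adjusted p = 0.166 with an estimated correlation. Of 16 glycolysis and hypoxia genes 14 fell (adjusted p = 0.00505, and adjusted p = 0.674 with an estimated correlation), with Bnip3 at -2.25 ± 0.51 and Egln3 at -2.05 ± 0.37. Of 20 proliferation genes 14 rose and none fell (16 adjusted over the list alone), with the replication helicase subunits Mcm5 at 0.54 ± 0.16 and Mcm3 at 0.50 ± 0.14 (adjusted p = 0.000995, and adjusted p = 0.672 with an estimated correlation). Of 15 YAP targets 8 rose and 1 fell, with the EGF receptor ligands Ereg at 1.70 ± 0.20 and Areg at 1.3 ± 0.14 (adjusted p = 0.00265, and adjusted p = 0.258 with an estimated correlation). Of 12 enterocyte genes 7 rose and 3 fell (7 and 4 adjusted over the list alone), with the alkaline phosphatase Alpi at 1.70 ± 0.15 and the aminopeptidase Anpep at -3.94 ± 0.49 (adjusted p = 0.0406, and adjusted p = 0.248 with an estimated correlation). That call was lost without the doubted libraries (adjusted p = 0.0576) and with set means as units (adjusted p = 0.255). The immune cell list fell in 3 of 3 (adjusted p = 0.0302, and adjusted p = 0.319 with an estimated correlation).

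The secretory lists held members that moved apart and were not called. In the goblet list the trefoil peptide Tff3 rose (2.5 ± 0.29, from 47 to 229 TPM) while Fcgbp (-3.31 ± 0.43) and Spink4 (-2.75 ± 0.28) fell (3 rose and 4 fell of 7). In the Paneth list Mmp7 (-1.68 ± 0.19) and the lectin Itln1 (-1.25 ± 0.16) fell (2 rose and 4 fell of 7). In the core clock list 6 rose and 7 fell of 20 (6 and 8 adjusted over the list alone), with Npas2 at 1.60 ± 0.24, Nr1d2 at -1.60 ± 0.15, Cry1 at 1.38 ± 0.13, Per2 at 1.18 ± 0.11 and Nr1d1 at -0.75 ± 0.13 (adjusted p = 0.813). Interferon genes fell in 6 of 7 and rose in 1, with Mx1 at -1.47 ± 0.19 (adjusted p = 0.0614), tuft cell genes fell in 4 of 4 (adjusted p = 0.121), and glucocorticoid response genes fell in 7 of 11 and rose in 2 (adjusted p = 0.281). The heat shock list rose in 6 of 9 and fell in 2, with Hspb1 at -1.79 ± 0.19. Of the markers of other cell types, the fibroblast gene Vim (-1.53 ± 0.18), the endothelial genes Cdh5 (-1.27 ± 0.32) and Esam (-0.94 ± 0.23) and the immune gene Cd68 (-0.57 ± 0.11) fell, and the smooth muscle gene Acta2 rose (1.32 ± 0.15, from 2.07 to 7.38 TPM). The majority direction turned with median-of-ratios scaling in the p53 list (1 rose and 4 fell, then 5 and 4) and with quantile normalization in the Notch list (1 and 2, then 3 and 2). Median, mean and test differed in sign for the E-box, Hippo, Notch, colon, core clock and gastric lists, none of them called.

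The Bmal1 effect on level differed between Apc genotypes for 841 of 13846 genes at 2-fold or more (interaction in limma, 246 higher and 595 lower). Tmem252 (-1.76 ± 0.06, SE), Cldn8 (-1.70 ± 0.10), Cyp3a11 (-1.21 ± 0.07), the leucine-rich repeat gene Lingo4 (-0.93 ± 0.04), BC018473 (-0.87 ± 0.06) and Plbd1 (-2.58 ± 0.19) were among the genes with a lower Bmal1 effect in Apc-min organoids. Anxa10 (4.44 ± 0.32) and the cytochrome Cyp4b1 (1.60 ± 0.11) had a higher effect (adjusted p = 1.11e-40 to 4.12e-19). Tmem252 and Cyp3a11 averaged under 1 TPM in both Apc-min genotypes and were not tested there. Their interactions thus rest on their rises in organoids WT for Apc. Igfbp4 fell by 2.13 in organoids WT for Apc and rose by 0.66 ± 0.22 in Apc-min organoids. The fall of Nr1d1 was smaller in Apc-min organoids (interaction 1.59, adjusted p = 1.35e-12), while the interactions of Cry1 (0.14, adjusted p = 0.456) and Nr1d2 (0.30, adjusted p = 0.178) did not pass. Of 11690 genes tested in both backgrounds, 3 rose and 8 fell at least 2-fold in both, where independent lists would share 0.10 and 0.28, and the effects had a Pearson r of 0.11 and a Spearman rho of 0.04 across genes, which are not independent replicates. Without the doubted libraries 1032 interactions were called, with quantile normalization the split was 315 higher and 462 lower, with a pseudocount of 0.1 there were 1476, and with means of library sets as units 357.

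**Figure D3:**
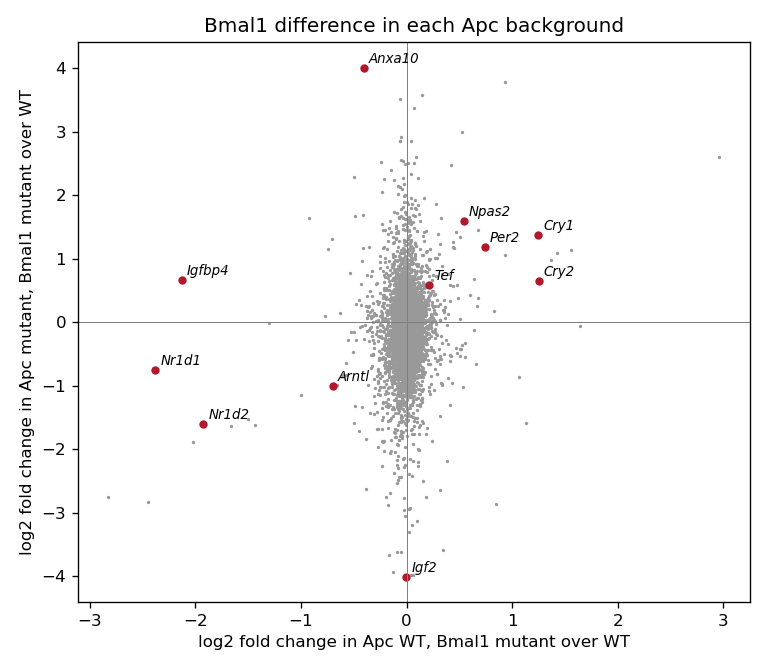
Log2 fold change of Bmal1-null over Bmal1 WT organoids in Apc WT (horizontal) against Apc-min (vertical), 1 point per gene, 11690 genes, with named genes marked. Nr1d2 and Cry1 lie away from 0 on both axes, and Igfbp4 lies mainly on the horizontal one.

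Transcripts of differentiated intestinal cells were lower in Apc-min than in control organoids, and fetal and regenerative genes were higher. The apolipoprotein Apoa1 fell by 11.61 ± 0.06 on the log2 scale against control organoids (SE, n = 22 per genotype), from 4323 to 0.402 TPM, sucrase-isomaltase Sis by 9.6 ± 0.05, and the stem cell marker Olfm4 by 9.12 ± 0.07, from 577 to 0.0218 TPM. The interferon-induced membrane protein Ifitm1 rose by 10.34 ± 0.17, from 0.129 to 1662 TPM, and the endodermal factor Sox17 by 8.63 ± 0.12. In limma 3349 of 13663 genes differed at least 2-fold, 1654 higher and 1695 lower, and 11153 passed the adjusted p alone, with 3364 at 2-fold without the doubted libraries. The split was 1378 higher and 1928 lower with median-of-ratios scaling and 1493 and 1979 with the slope on gene length as a covariate. The median of all genes was 0.17 with TPM and 0.01 with median-of-ratios scaling, and changes stand relative to that shift.

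The other largest rises were Krt14 (8.82 ± 0.16), the retinol transporter Stra6 (8.07 ± 0.27), the small heat shock protein Cryab (7.87 ± 0.12), gastric lipase Lipf (7.64 ± 0.41), Krt4 (7.53 ± 0.10), the imprinted RNA H19 (7.31 ± 0.32), the aldehyde dehydrogenase Aldh3a1 (7.19 ± 0.16) and Ly6c1 (6.91 ± 0.13). Among the other largest falls were Ang4 (-9.73 ± 0.06) and the Paneth cell defensins Defa24 (-11.50 ± 0.18, from 10160 to 3.01 TPM), Defa30 (-10.71 ± 0.09), Defa22 (-9.75 ± 0.12), Defa17 (-9.47 ± 0.09) and Defa21 (-9.25 ± 0.14), whose near-identical sequences share reads and make the single values uncertain. All had the same sign at the 12 time points. Of the 3349 genes, 2555 (76.3%) were 2-fold in all 4 pairs of library sets.

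Every tested member fell in the enterocyte (20 of 20, adjusted p = 3.6e-13), enteroendocrine (14 of 14, adjusted p = 5.87e-13), goblet (11 of 11, adjusted p = 1.59e-09) and ileum lists (5 of 5, adjusted p = 2e-05). Examples were Apoa4 (-9.09 ± 0.16), the proglucagon gene Gcg (-8.01 ± 0.05), peptide YY Pyy (-6.92 ± 0.06), the mucin Muc2 (-7.27 ± 0.11), Zg16 (-8.04 ± 0.12) and the ileal bile acid carriers Slc51a (-7.79 ± 0.08) and Fabp6 (-7.55 ± 0.13). Paneth genes fell in 12 of 14 and rose in 2 (adjusted p = 2.42e-09), and PPAR targets fell in 11 of 12 (adjusted p = 4.03e-06), with Creb3l3 at -6.47 ± 0.07. Fetal and regenerative markers rose in 12 of 13 and fell in 1 (adjusted p = 1.05e-05), with Clu at 4.96 ± 0.10 and Anxa10 at -4.08 ± 0.20. With an estimated correlation these 7 lists kept adjusted p = 3.58e-06 to 0.0394.

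Of 20 Wnt targets 16 rose and 4 fell (adjusted p = 0.00528, and adjusted p = 0.466 with an estimated correlation), with Notum at 6.37 ± 0.29, Nkd1 at 4.69 ± 0.22 and cyclin Ccnd1 at 2.69 ± 0.07. Of 17 stem cell genes 7 rose and 10 fell (adjusted p = 0.428), and Lgr5 averaged 29.9 TPM ± 8.13 in control and 10.9 TPM ± 8.67 in Apc-min organoids (SD, n = 22 each). Hippo pathway components rose in 14 of 19 and fell in 2, with the coactivator gene Wwtr1 (TAZ) at 3.89 ± 0.04 (adjusted p = 0.0243, and adjusted p = 0.731 with an estimated correlation). YAP targets rose in 11 of 15 and fell in 3, with Ccn2 at 4.76 ± 0.08 and the cytokine Il33 at 4.50 ± 0.12 (adjusted p = 0.0302, and adjusted p = 0.385 with an estimated correlation). All 20 proliferation genes rose (17 with median-of-ratios scaling), with the mitotic kinase Bub1 at 1.13 ± 0.12 (adjusted p = 0.0371, and adjusted p = 0.797 with an estimated correlation). p53 targets rose in 12 of 14, with Phlda3 at 3.85 ± 0.04 and Eda2r at 3.78 ± 0.10 (adjusted p = 0.000104, and adjusted p = 0.119 with an estimated correlation). All 9 heat shock genes rose, with Hspb1 at 5.55 ± 0.14 (adjusted p = 0.00394, and adjusted p = 0.119 with an estimated correlation), as did 4 of 4 gastric genes, with the trefoil peptides Tff2 at 4.94 ± 0.22 and Tff1 at 4.43 ± 0.27 (adjusted p = 0.0348, and adjusted p = 0.494 with an estimated correlation). The YAP call was lost without the doubted libraries (adjusted p = 0.052). With set means as units the YAP, gastric and proliferation calls were lost (adjusted p = 0.0613, 0.0608 and 0.061).

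Lists that fell on balance included cholesterol synthesis (2 rose and 15 fell of 19, adjusted p = 0.00505), tuft cell (1 and 9 of 10, adjusted p = 0.00174), glucocorticoid response (2 and 8 of 12, adjusted p = 0.00853), unfolded protein response (2 and 9 of 12, adjusted p = 0.0292), colon epithelium (1 and 4 of 5, adjusted p = 0.0371) and REV-ERB and ROR clock targets (0 and 5 of 6, adjusted p = 0.0306). These calls were lost with an estimated correlation, at adjusted p = 0.574, 0.237, 0.366, 0.5, 0.248 and 0.288 in that order. Members included the actin-binding tuft gene Avil, which rose by 3.94 ± 0.22, the metallothioneins Mt2 (-3.40 ± 0.05) and Mt1 (-2.76 ± 0.06), the stress factor Ddit3 (-1.96 ± 0.21) and the anion exchanger Slc26a3 (-5.32 ± 0.07). Lists not called were core clock (3 rose and 9 fell of 20, adjusted p = 0.122), E-box clock targets (0 and 4 of 12), Notch (4 and 5 of 11, with Atoh1 at -4.99 ± 0.06), interferon response (2 and 5 of 9), inflammation and antimicrobial (4 and 6 of 10, with Reg3b at -7.98 ± 0.16), proximal small intestine (2 and 3 of 6), histones (1 and 3 of 6), sex-linked (3 and 0 of 4), mitochondrially encoded (0 and 1 of 7) and immune cell (3 and 0 of 3). The glycolysis and hypoxia list went both ways (6 and 6 of 16, and 3 and 7 with median-of-ratios scaling), with a median of 0.05 and a mean of -0.21. The mitochondrial list also had a median and a mean of opposite sign (0.04 and -0.02), and with quantile normalization 1 member rose and none fell. Of other cell types, Cd68 (2.19 ± 0.12), Lyz2 (2.18 ± 0.16), Cdh5 (2.61 ± 0.26), Esam (1.88 ± 0.19) and Acta2 (1.38 ± 0.14) rose and Vim fell (-0.49 ± 0.10). No neuron or glia marker was high enough to be tested. Adjusted over the list alone, 30 of the 32 lists had the same counts and the others differed by 1 member.

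**Figure D4:**
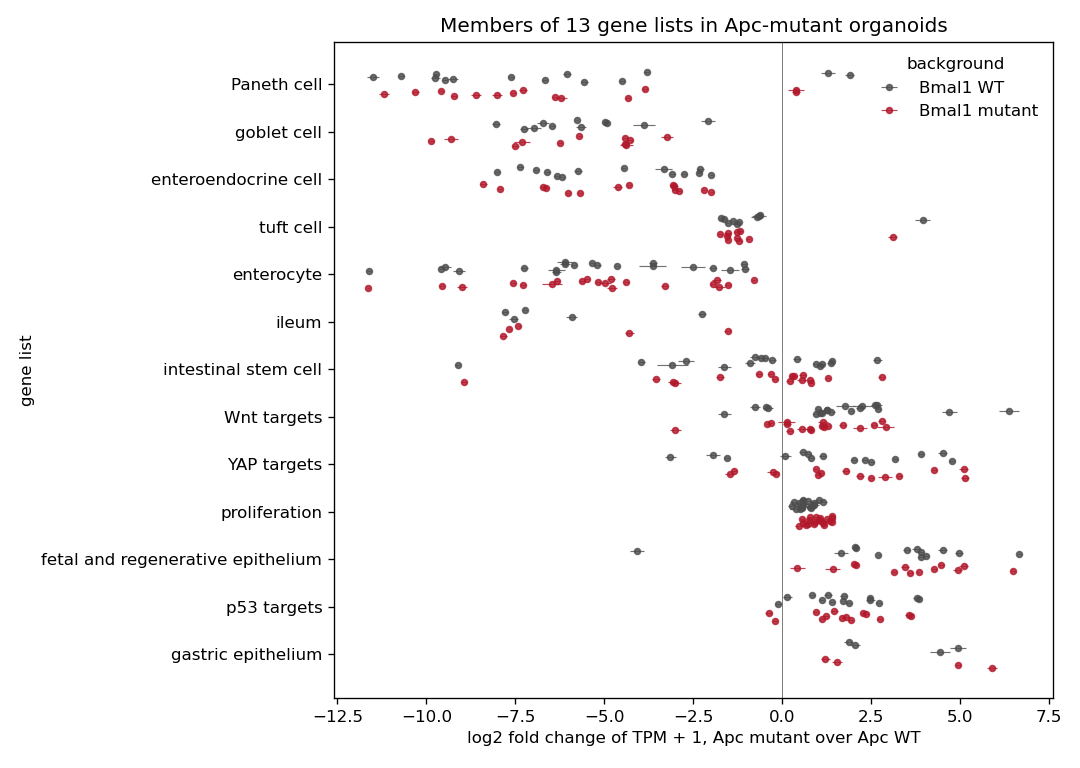
Log2 fold change of Apc-min over Apc WT organoids for members of 13 gene lists, points with SE bars, in the Bmal1 WT and the Bmal1-null background. Enterocyte, goblet and enteroendocrine members lie below 0 in both, and the fetal and regenerative members lie above 0 apart from Anxa10 in Bmal1 WT.

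The Apc comparison in Bmal1-null organoids gave much the same picture. Ifitm1 (8.11 ± 0.16), Sox17 (7.42 ± 0.11), Cryab (6.79 ± 0.10), the matrix protein Efemp1 (6.74 ± 0.04), transglutaminase Tgm1 (6.64 ± 0.06), Krt4 (6.47 ± 0.10), Wfdc2 (6.35 ± 0.20), Crip2 (6.06 ± 0.06) and Tff1 (5.90 ± 0.14) were among those that rose the most on the log2 scale (SE, n = 22 per genotype). Apoa1 (-11.64 ± 0.04), Defa24 (-11.19 ± 0.14), the guanylin genes Guca2a (-10.45 ± 0.16) and Guca2b (-9.02 ± 0.07), Defa30 (-10.31 ± 0.09), Zg16 (-9.86 ± 0.06), Ang4 (-9.60 ± 0.06), Sis (-9.57 ± 0.07), Spink4 (-9.30 ± 0.19) and Defa17 (-9.23 ± 0.08) fell the most. In limma 3541 of 13404 genes differed at least 2-fold, 1552 higher and 1989 lower, with 11327 at the adjusted p alone and 3582 at 2-fold without the doubted libraries. With quantile normalization the split was 1794 higher and 1759 lower, so the majority turned, and with the slope on gene length as a covariate it was 1318 and 2524. Of 13220 genes tested in both backgrounds 1080 rose and 1489 fell in both, where independent lists would share 166.6 and 252.3, and 8 went opposite ways. The Pearson r of the effects across genes, which are not independent replicates, was 0.93.

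Enterocyte (20 of 20), enteroendocrine (14 of 14), goblet (11 of 11), Paneth (12 of 14), ileum (5 of 5) and PPAR lists (11 of 12) fell again and kept adjusted p = 4.66e-05 to 0.0466 with an estimated correlation. Proliferation genes rose in 20 of 20, with Rrm2 at 1.39 ± 0.06 (adjusted p = 5.7e-06, and adjusted p = 0.422 with an estimated correlation), fetal and regenerative genes in 12 of 13 (adjusted p = 1.14e-06, and adjusted p = 0.0948 with an estimated correlation), and p53 targets in 12 of 14 with 2 falling (adjusted p = 0.000261, and adjusted p = 0.237 with an estimated correlation). Heat shock (9 of 9), gastric (4 of 4), YAP target (11 of 15, 2 fell), Hippo (15 of 19, 1 fell) and Wnt target lists (12 of 18, 3 fell) rose at adjusted p = 0.000582 to 0.0469. They were lost at adjusted p = 0.064, 0.0761, 0.335, 0.731 and 0.731 with an estimated correlation, in that order. Notum rose by 2.90 ± 0.24, against 6.37 in the Bmal1 WT background, and Lgr5 fell by 3.01 ± 0.16. Glucocorticoid response (10 of 12 fell), tuft (9 of 10), colon (4 of 5) and REV-ERB and ROR target lists (5 of 6) fell at adjusted p = 0.00205 to 0.0493 and were lost at adjusted p = 0.336, 0.237, 0.237 and 0.5 with an estimated correlation. The REV-ERB and ROR target call was lost without the doubted libraries (adjusted p = 0.0509), and the colon and gastric calls with set means as units (adjusted p = 0.0843 and 0.0608). Cholesterol synthesis (13 of 19 fell, adjusted p = 0.0676) and unfolded protein response genes (9 of 12 fell, adjusted p = 0.104) were not called here. The E-box list had 4 rises and 5 falls, and 6 and 5 with quantile normalization, and the stem cell and sex-linked lists had a median above 0 and a downward test, none of them called.

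Fitted 24 h time courses also differed between Apc genotypes, though no gene passed once a linear time term was added. Against control organoids, 1684 of 13663 genes in Apc-min organoids passed limma's interaction test (4356 at an unadjusted p under 0.05). Tmem252 had the lowest adjusted p (0.000139), followed at 0.0113 by the interferon regulatory factor Irf8, Atp7b, Hif3a, the signal transducer Stat6, Lpin1, the nucleoside transporter Slc28a3, Dglucy, the ceramide kinase Cerk and Prickle3. For Tmem252 the time course in control organoids was set against a mean under 1 TPM in Apc-min organoids. Of 20 clock genes 10 passed, among them Tef (0.0172), Per3 (0.0207), Nr1d2 (0.0218), Ciart (0.0221), Cry2 (0.023), Per1 (0.0277), Bhlhe40 (0.0426), Nr1d1 (0.0427) and Csnk1d (0.0438), and 12 adjusted over the list alone. With a linear time term 0 genes passed (431 at an unadjusted p under 0.05), and without the doubted libraries 815. Without Apc-min 28 h replicate 1, 28 h replicate 2, 30 h replicate 1, 32 h replicate 2, 38 h replicate 1 or 42 h replicate 1 the count was 815, 907, 2681, 974, 628 or 626. Without control 24 h replicate 2, 26 h replicate 1, 28 h replicate 2, 30 h replicate 1, 38 h replicate 1 or 40 h replicate 2 it was 2537, 1003, 854, 739, 540 or 303. With the lower- or higher-numbered library as a term it was 4914 (6468 unadjusted), and with no filter on low values 415.

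In the Bmal1-null background 112 of 13404 genes passed the same test (1213 at an unadjusted p under 0.05). Nlrp6, the nucleotidase Entpd8 and Sept5 (adjusted p = 0.00197 each in limma) led the list, with the leukotriene receptor Ltb4r2, Ms4a18, Engase, the crystallin Cryl1, the phosphatase inhibitor Ppp1r1b, the aldehyde dehydrogenase Aldh1b1 and Tcstv1 (adjusted p = 0.00198 to 0.00531). Of 19 clock genes 1 passed, and 2 passed adjusted over the list alone. With a linear time term 0 genes passed (183 at an unadjusted p under 0.05), and without the doubted libraries 368. Without Apc-min Bmal1-null 26 h replicate 1, 28 h replicate 1, 44 h replicate 1 or 44 h replicate 2 the count was 73, 368, 73 or 70. Without Bmal1-null 28 h replicate 1, 32 h replicate 1, 38 h replicate 1, 38 h replicate 2, 42 h replicate 2 or 44 h replicate 2 it was 59, 71, 69, 59, 68 or 70, and with no filter on low values it was 61.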

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

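The explanations and tests of the swapped labels, mixed material, one-way drift, clock output, organoid lines and imprinted genes were chosen only after the results were seen, and those of depth, length bias, whole chromosomes and random splits before their outcomes were known. Removing the genotype means from the list splits was chosen after the splits without it were seen.

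The pair of Apc-min libraries at 28 h scored 0.991 and -0.233 on the Bmal1 axis, each within the range of the other label, which is consistent with swapped labels at a score of 0.991. Mixed material of both genotypes would have placed both between the groups, and the larger distance from the labelled group was 1.23. Low depth was argued against, with 0 of the 2 libraries outside the range of the others (33.24 and 36.38 M uniquely mapped reads).

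Of the genes called rhythmic, 98.7% in Apc-min and 98.7% in Apc-min Bmal1-null organoids peaked within 3 h of the times a one-way drift gives. At an unadjusted p under 0.05 the share was also high in control (95.6%) and Bmal1-null organoids (90.9%). A straight line left the smaller residual for 45.7% and 50.6% of the genes called in Apc-min and Apc-min Bmal1-null organoids. The cosine fit has a term more than the line, so these shares do not count against drift, which stays open. Of the genes called in Apc-min organoids, 87.9% (1276 of 1451) peaked within 3 h of the same time in Apc-min Bmal1-null organoids. Random pairing of the peak times gives 59.2%. The agreement above random pairing shows that part of the time course was shared with organoids null for Bmal1. It cannot decide whether the calls hold clock output that needs Bmal1. Of the called genes, 98.7% peaked at the times a drift gives, and a shared drift would add to the agreement. Such output stays open. Of the 4 clock genes called in control organoids 0 were called in Apc-min organoids. A gene that does not pass can still cycle, and the fit had no term for the library sets. This count therefore cannot decide whether the clock output was the same. Length bias as the source of the Apc-min count was argued against, as 5658 genes passed with the slope on gene length as a covariate. The counts still depend on that slope, as they also rose in control (7 to 52), Bmal1-null (0 to 172) and Apc-min Bmal1-null organoids (316 to 1219). Without the doubted libraries the count rose from 316 to 1444 in Apc-min Bmal1-null organoids. This argues against swapped labels as a source of the calls there, but not against a swap, as a mislabelled library can also hide calls. In Apc-min organoids the count fell from 1513 to 401, and swapped labels as a source of calls stay open there.

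The larger number of 2-fold Bmal1 differences in Apc-min organoids (827 against 21) may reflect a difference between organoid lines, as 510 genes differed 2-fold between the lower- and higher-numbered libraries within Apc-min organoids and 47 within Apc-min Bmal1-null organoids (717 and 57 without the doubted libraries). This stays open, as the line of each library is not labelled. For whole chromosomes the highest ratio of called to tested share was 1.27. That share counts only 2-fold genes and would miss a smaller shift of a whole chromosome. The median log2 difference per autosome ran only from -0.09 (chromosome 7) to 0.02 (chromosome 16), which argues against such a shift. Swapped labels do not account for it, with 1021 genes without the doubted libraries.

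Effects that differ between groups included the 841 genes with an Apc by Bmal1 interaction. On the log2 scale it was -1.76 for Tmem252, -0.93 for Lingo4, -1.7 for Cldn8 and -1.21 for Cyp3a11. It was 1.6 for Cyp4b1, 4.44 for Anxa10, -0.87 for BC018473, -2.58 for Plbd1, 1 for Npas2 and 1.59 for Nr1d1. Tmem252 and Cyp3a11 were below the mean of 1 TPM needed for a test between the Apc-min genotypes. The rhythm difference test called 5 genes between control and Bmal1-null organoids, 1684 between control and Apc-min, and 112 between Bmal1-null and Apc-min Bmal1-null organoids. With a linear time term these counts were 1, 0 and 0.

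Random orders of the time labels gave as many rhythmic genes in 3 of 100 for control organoids (7 genes, highest other 988), 100 for Bmal1-null (0, 5549), 4 for Apc-min (1513, 4787) and 2 for Apc-min Bmal1-null (316, 805), the real order included. Some orders thus called several times the real count, which points to a structure of the samples. Splits gave as many rhythm differences in 1 of 100 for Bmal1 in Apc WT (5, highest other 0), 100 for Bmal1 in Apc-min (0, 7084), 2 for Apc in Bmal1 WT (1684, 3693) and 2 for Apc in Bmal1-null (112, 1770). For mean level the real labels gave the most genes in all 4 comparisons and the interaction, 1 of 100 each, with highest others of 0, 399, 6, 1125 and 0. For gene list tests adjusted within each comparison as many lists were called in 39, 37, 5 and 6 of 100 (5, 5, 20 and 19 real, against 6, 7, 20 and 18 adjusted over all comparisons, highest others 13, 11, 23 and 20), which decides nothing, as uneven splits carry part of the genotype difference. With each genotype's mean removed it was 48, 55, 1 and 1 of 100 (highest others 12, 12, 14 and 13). The number of lists adjusted in this way could thus have arisen by chance for Bmal1, while for Apc only the real split reached it. The splits treat libraries as units, so they leave chance between lines untested, and Apc also moves with medium and library series.

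Of 8 tested imprinted genes, listed after H19, Igf2 and Grb10 had been seen, 5 were higher in Apc-min than in control organoids. These include the 3 genes that prompted the list, and of the others Plagl1 and Igf2r were higher and Dlk1 (-3.16) and Cdkn1c (-0.16) lower. Between Apc-min Bmal1-null and Apc-min organoids H19 fell by 6.4 ± 0.52, Igf2 by 4 ± 0.33 and Grb10 by 2.88 ± 0.24, and the list cannot test a reactivated imprinted network. In Apc-min Bmal1-null organoids H19 averaged 16.9 TPM in the lower-numbered libraries, which include a doubted one, and 0.503 TPM in the higher-numbered.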

How the results depend on the processing

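The fits without libraries 9 and 10 and with the slope on gene length as a covariate were chosen only after results were seen, and the cause of the differences below was not tested.

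Rhythmic genes in control organoids (7) were 11 with no filter, 4 at 5 TPM or more, 30 with median-of-ratios scaling, 45 in the authors' quantile-normalized table, 4 with a linear time term, 2 with time as a factor, 289 with the lower- or higher-numbered library as a term, 52 with the length slope and 4 to 50 without 1 library. In Bmal1-null organoids (0) they were 7 in the quantile-normalized table, 25 with time as a factor, 172 with the length slope and 0 to 10 without 1 library. In Apc-min organoids (1513) they were 587 with no filter, 797 in the quantile-normalized table, 0 with a linear time term or time as a factor, 4179 with the library term, 5658 with the length slope, 401 without libraries 9 and 10 and 401 to 2643 without 1 library. In Apc-min Bmal1-null organoids (316) they were 0 with a linear term, 2 with time as a factor, 1219 with the length slope, 1444 without libraries 9 and 10 and 151 to 1444 without 1 library. The lower- and higher-numbered libraries alone gave 0 and 0 in control, 0 and 0 in Apc-min, and 0 and 81 in Apc-min Bmal1-null organoids.

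Rhythmic clock genes were 11, 5 and 22 adjusted over the list alone in control, Apc-min and all organoids. With a linear term they were 0 in each Apc-min genotype and 3 in all, and without libraries 9 and 10 they were 0 and 8. Without 1 library they ranged from 2 to 5 in control, 0 to 5 in Apc-min and 2 to 8 in Apc-min Bmal1-null organoids.

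Rhythm differences for Bmal1 in Apc WT (5) were 3 with a pseudocount of 0.1, 0 with no filter, 1 with a linear term or all 88 libraries and 0 to 5 without 1 library. For Bmal1 in Apc-min (0) they were 4 with the library term, 13 with all 88 libraries and 0 to 2 without 1 library. For Apc in Bmal1 WT (1684) they were 415 with no filter, 0 with a linear term, 4914 with the library term, 815 without libraries 9 and 10 and 303 to 2681 without 1 library. For Apc in Bmal1-null (112) they were 61 with no filter, 0 with a linear term, 368 without libraries 9 and 10 and 59 to 368 without 1 library.

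Level differences of Bmal1 in Apc WT (21) were 34 with a pseudocount of 0.1 and 7 with set means as units. In Apc-min (827) they were 1319 with that pseudocount, and interactions (841) were 1476 with it and 357 with set means. With the length slope Uty and Kdm5d turned from 0.27 and 0.16 to -0.0676 and -0.251 for Apc in Bmal1 WT. List calls (51) were 16 with an estimated correlation. With set means as units 42 of the 51 were kept. With library sets as blocks the counts at 2-fold were 21, 727, 3329 and 3537 in the 4 comparisons of level and 827 for the interaction.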

Other observations

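The lists of this part were fixed before the data were examined, while the test of their change over the series was chosen only after rhythm results were seen.

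Fetal and regenerative genes fell over the series in both genotypes WT for Apc, 8 of 8 in each, by a median of 0.83 and 0.89 on the log2 scale from 24 to 46 h. The list was called in both with an estimated correlation (adjusted p = 0.00177 and 0.000174, limma). The stem cell marker Olfm4 rose there by 1.03 and 1.21. In Apc-min and Apc-min Bmal1-null organoids 2 and 5 of 13 fetal and regenerative genes fell and 0 rose. The list was called downward in both at the preset correlation (camera, adjusted p = 0.0192 and 2.22e-07). With an estimated correlation it was not (adjusted p = 0.171 and 0.245).

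Glycolysis and hypoxia genes rose in Apc-min (16 of 16, median 1.32) and Apc-min Bmal1-null organoids (13 of 16, median 0.83), with adjusted p = 1.12e-08 and 8.56e-11 in limma, and adjusted p = 0.376 and 0.326 with an estimated correlation. Lgr5 rose by 1.95 and 1.65 in the same genotypes and Smoc2 by 2.53 in Apc-min Bmal1-null organoids. A linear slope was called for 276, 842, 3943 and 1030 genes in control, Bmal1-null, Apc-min and Apc-min Bmal1-null organoids.

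The slope on gene length was compared with the first principal component of the libraries in each genotype (4 relations, n = 22 each, in the order control, Bmal1-null, Apc-min and Apc-min Bmal1-null). In Apc-min organoids the relation passed for Pearson and not for Spearman. Pearson r was 0.995, 0.989, 0.502 and 0.874 and Spearman rho 0.988, 0.963, 0.372 and 0.936. Permutation p over 100000 orders was 1e-05, 1e-05, 0.018 and 1e-05 for Pearson, and 1e-05, 1e-05, 0.089 and 1e-05 for Spearman, where 1e-05 is the lowest possible. Adjusted they were 1.3e-05, 1.3e-05, 0.018 and 1.3e-05, and 1.3e-05, 1.3e-05, 0.089 and 1.3e-05. Without the 2 farthest libraries r was 0.993, 0.988, 0.353 and 0.647.

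Between the lower- and higher-numbered libraries 30, 10, 510 and 47 genes differed 2-fold in control, Bmal1-null, Apc-min and Apc-min Bmal1-null organoids, and 717 and 57 in the last pair without the doubted libraries. In both Bmal1-null genotypes the higher-numbered set held Xist (11 of 11 and 10 of 10 libraries) and the lower-numbered set Y-linked transcripts.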
